A study of Sus scrofa with 325 samples.

How the data were processed

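RNA from the *Longissimus lumborum* muscle (the loin muscle along the spine) of 325 pigs was measured on a custom Agilent array with 1 dye, 1 array per animal. Per the labels' protocols, total RNA was extracted with Trizol and 500 ng per animal was labelled with Cy3. The pigs were females and castrated males of an F2 intercross between a Pietrain-type sire line and a synthetic sire line. The labels give each array a sex, an animal number and a slide number. They placed 165 arrays in the female group and 160 in the male group, on 41 slides, of which 38 held 8 arrays and 3 held 7. Slide numbers ran from 1 to 11 and from 23 to 53. Both labelled sexes were present on 40 slides, and slide 24 held only arrays labelled female. Litter and sire were not used here, so animals were treated as independent although F2 animals may be sibs, which can make p-values too small.

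The deposited values are 1 table of 7905 probes by 325 arrays, taken here as log2 values as the authors had processed them. All columns matched a sample by name, and 0 columns were left unmatched. The log base is not given in the sources used here. Base 2 was assumed from the range, natural logarithms cannot be excluded, and differences are therefore given on the deposited log scale without fold changes. The scanner software, background correction, normalisation and filter on dim spots are not given in the sources used here. Values were not centred per probe, since probe means ran from -2.80 to 7.38. Array medians ran from -1.02 to -0.70. The table left 32732 cells empty (1.27%), between 2 and 832 per array with a median of 43, and 1038 probes had a value on every array. Empty cells were kept as missing. No 2 arrays held identical values. Signal over background was not used here, and the number of arrays limits the precision.

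None of the probe names (0 of 7905) matched an identifier in the gene tables used, and the files do not pair probes with genes. The 33 muscle gene lists fixed beforehand could therefore not be tested, nor could relations between them, the restriction to probes with 1 gene symbol or the averaging of probes of one gene. The rule for named genes had been written for symbols. In its place, after the probe names had been seen, the 2 probes with the largest positive and the 2 with the largest negative difference among those past the threshold are given by probe name, together with the first probes in the rankings by spread and by BIC gain.

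Sex differences were tested per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as labelled female minus labelled male with slide as a fixed block. P-values were adjusted by the Benjamini-Hochberg method over all probes, and probes with an adjusted p under 0.05 were counted. Slide differences were tested with limma's moderated F-test with labelled sex in the model, over the 7839 probes with a value on every slide, and 66 probes were left out. The share of variance between slides is the fall in residual sum of squares when slide is added to labelled sex. The spread between animals is the SD per probe after slide and labelled sex were removed. Separate clusters were sought with equal-variance Gaussian mixtures of up to 3 components (mclust 6.1.1) on the same adjusted values. A probe was counted when the BIC gained more than 10 over 1 component, neighbouring means lay more than 3 within-cluster SDs apart and each cluster held at least 5% of the arrays. These tests, their thresholds and the alternatives to them, except those said to be later, were chosen before the data were examined. Other steps were chosen after the values had been seen. Counted probes were grouped by average linkage on absolute correlation, at 0.5. For probes with a wide gap between low and high values, arrays were divided at the midpoint between the means of both sides. This served to count arrays per slide and set them beside the sex labels. The same division was used to count clusters of BP153836.1_434 and CF179208.1_1029 per slide. It was also applied to the mean level of the largest group of correlated probes. No array was given a sex from its values, and no other probe was tested between the classes set beside the sex labels.

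The sex test was tested on simulated data with the real slides and labels, over 7905 probes with 50 changed at each size. It recovered 66% of probes changed by 0.1, 92% at 0.2, and 100% at 0.4 and at 0.8, with 6 false calls among 185. The simulation took the labels as right and gave each probe independent normal noise. These rates therefore do not hold where labels and arrays are mismatched or probes move together. Of 1000 simulated normal probes the cluster rule counted 0%, and of 1000 with heavier tails (t distribution) 0.1%. It counted 80.5% of 200 probes simulated as a 1:3 mixture with means 4 SDs apart, and 0% with means 2 SDs apart.

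Alternatives for the sex test were no slide term, slide as a random block, array quality weights, robust regression, quantile normalisation, subtraction of array medians, removal of the dimmest 25% of probes, the animal number series as a covariate, subsets of slides, each slide left out in turn, a Welch test per probe and a minimum difference of 0.2. A regression on slide means and the averaging of probes of one sequence name were added after the data had been seen. Permutation tests used 100000 resamples and were two-sided unless stated. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.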

Results

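Muscle transcripts of 325 F2 pigs were measured on 7905 probes, in 165 arrays labelled female and 160 labelled male. The cross had been set up to map loci for quantitative traits, and the labels allow a comparison of the sexes, of the 41 slides, and of animals with one another. Over the 1038 probes measured everywhere, pairs of arrays correlated across probes with a median r of 0.954 (range 0.896 to 0.990). Pairs on the same slide had a median r of 0.968 and pairs on different slides 0.954.

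The sex comparison asked which transcripts differed between loin muscle of females and of castrated males. Few did by the labels. These labels matched the 2 groups of arrays described below on 148 of 325 arrays. If those groups follow sex, as their numbers per slide do, the count cannot show how far the sexes themselves differ. At a threshold of 0.05 on the adjusted p, 7 of 7905 probes differed, 3 with higher and 4 with lower values in arrays labelled female. None of the 7 remained called with slide as a random block, on slides 1 to 11 alone or without a slide term, which gave 0, 0 and 1 probes. Probe CB286695.1_1794 was higher in arrays labelled female by 1.14 ± 0.23 (SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00334). Probe AJ938358.1_528 was higher by 0.57 ± 0.12 (SE; limma, Benjamini-Hochberg adjusted p = 0.00334). Probe CF175718.1_2364 was lower in arrays labelled female, with a difference of -0.80 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 0.00334). Probe BQ597859.1_1820 had a difference of -0.14 ± 0.03 (SE; limma, Benjamini-Hochberg adjusted p = 0.00407). All of these are on the deposited log scale, whose base was assumed to be 2. With slide as a random block the differences were 0.92, 0.47, -0.64 and -0.12 in that order, each with a limma adjusted p of 0.063. The files do not pair these probes with genes.

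On the deposited values, with slide differences kept, the means of the labelled sexes lay close together against the spread within each. The differences fitted with slide, given above, were larger but stayed below these SDs. For CB286695.1_1794 the mean was 1.34 ± 2.02 (SD) in the arrays labelled female, of which 1 had no value, and 0.99 ± 2.03 (SD, n = 160) in arrays labelled male. For AJ938358.1_528 it was -0.03 ± 0.98 (SD, n = 165) against -0.24 ± 1.03 (SD, n = 160). For CF175718.1_2364 it was -0.36 ± 1.41 (SD, n = 165) against -0.12 ± 1.39 (SD, n = 160), and for BQ597859.1_1820 it was 0.47 ± 0.27 (SD, n = 165) against 0.53 ± 0.27 (SD, n = 160). In the main fit there were 269 of 7905 probes at an unadjusted p under 0.05, fewer than the 395 that chance alone would give. Some other settings exceeded 395, with 480 in robust regression, 682 without a slide term, 677 by Welch test and 945 on slide means.

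**Figure D1:**
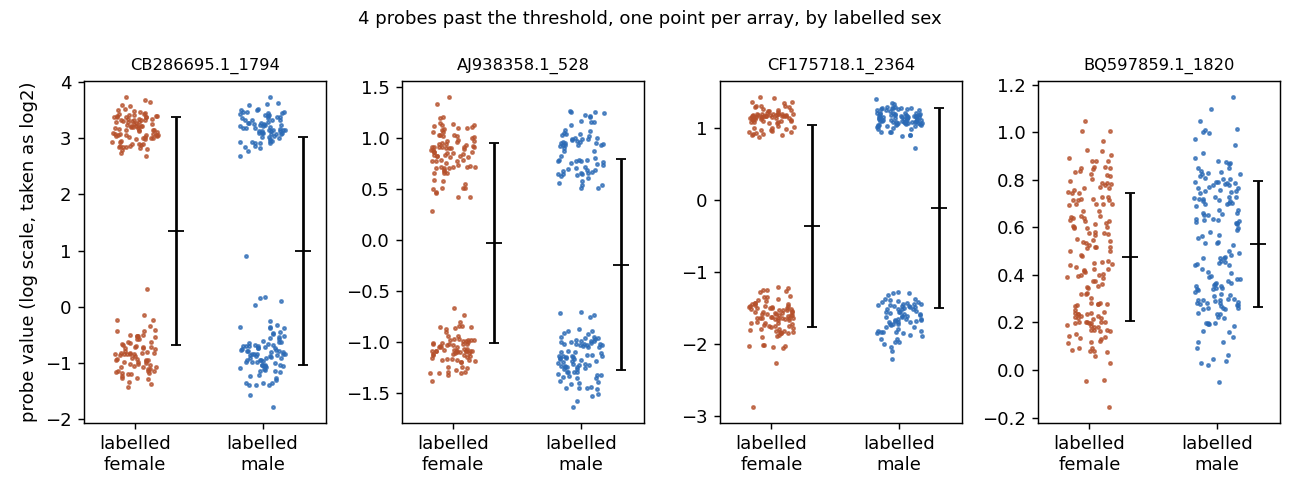
Values of the 4 named probes (y axis, deposited log scale taken as log2) in arrays labelled female and labelled male, 1 point per array, with the mean and SD of each labelled sex as bars. For CB286695.1_1794, AJ938358.1_528 and CF175718.1_2364 both labelled sexes hold arrays in each of 2 separate groups of values, and BQ597859.1_1820 shows no such gap.

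The spread had a particular form. CF175718.1_2364 divided the arrays into 161 with values up to -1.20 and the rest with values from 0.73 upward, with none between. AJ938358.1_528 had 161 arrays from 0.29 upward and the rest up to -0.66, and CB286695.1_1794 had 161 from 2.67 upward and the rest up to 0.90. Both of these probes were high on each array where CF175718.1_2364 was low and low where it was high, with 0 disagreements over 325 and 324 arrays. Arrays of both labelled sexes lay in both classes.

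Within slides and between slides, the sex labels gave opposite directions for all 4 named probes. Among the 40 slides with both labelled sexes, CB286695.1_1794 was higher in arrays labelled female on 30 and lower on 10. AJ938358.1_528 was higher on 28 and lower on 12, while CF175718.1_2364 and BQ597859.1_1820 were each higher on 10 and lower on 30. When slide means were regressed on the share of arrays labelled female, CB286695.1_1794 instead differed by -3.96 ± 0.18 between a slide of females and a slide of males (SE; limma, Benjamini-Hochberg adjusted p = 6.6e-21). The matching values were -1.75 for AJ938358.1_528, 2.77 for CF175718.1_2364 and 0.40 for BQ597859.1_1820, the last with a limma adjusted p of 0.104. Array by array, the direction of a sex difference in CB286695.1_1794, AJ938358.1_528 and CF175718.1_2364 is therefore not settled by these labels. The directions do not weigh the same, since totals per slide do not change when arrays of a slide are exchanged. Slide 24 held only arrays labelled female, and 0 of its 8 arrays were low for CF175718.1_2364. No exchange within that slide could change this. If totals per slide are right, slide 24 and the slide means argue against the direction within slides for those probes. The differences on slide means lay near the gaps between class means, which were -0.82 and 3.19, -1.12 and 0.86, and -1.64 and 1.14 in that order. The direction within slides rests on labels that matched the classes on 148 of 325 arrays. Slide means were examined after the data had been seen.

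Counts per slide showed the same relation. The number of arrays low for CF175718.1_2364 equalled the number labelled male on 36 of 41 slides and differed by 1 on the other 5. Array by array, however, low values fell on an array labelled male, or high values on one labelled female, in 148 of 325 arrays (45.5%). Labels shuffled within slides gave 186.5 on average (SD 8.43), a comparison that is not independent, since the probe had been chosen by its difference within slides. Across the 41 slides the share of low arrays and the share labelled male had a Pearson r of 0.971 and a Spearman rho of 0.957, each with a permutation p of 1.0e-05, the smallest that 100000 resamples can give. Without the 2 slides farthest from the median share r was 0.961. It was 0.887 over the 10 slides numbered 1 to 11 and 0.985 over the 31 slides numbered 23 to 53. No other correlation across slides was computed.

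**Figure D2:**
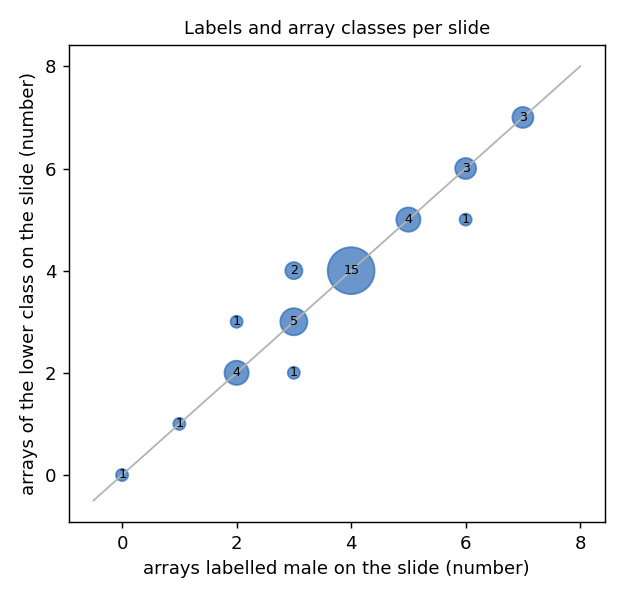
Number of arrays low for CF175718.1_2364 on each slide (y axis) against the number of arrays labelled male on it (x axis). The area and the number of each circle give the slides at that position, the line marks equal numbers, and 36 of 41 slides lie on it.

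Slides differed for most transcripts. With labelled sex in the model, 7369 of 7839 probes (94%) differed between the 41 slides at an adjusted p under 0.05 (limma's moderated F-test, Benjamini-Hochberg adjustment). The median probe had 35.3% of its variance between slides, where 12.4% would be expected without any slide effect. The 25th and 75th percentiles were 26.4% and 47.6%, and the 90th percentile was 61.6%. After quantile normalisation between arrays the median was still 34.4%. The labels do not say how animals were allotted to slides, so animal differences that follow the slides are included in these shares.

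**Figure D3:**
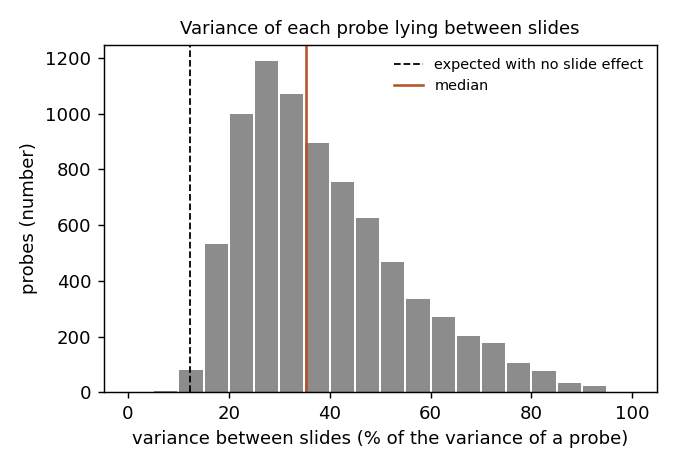
Number of probes (y axis) by the percentage of their variance that lay between slides (x axis), for 7839 probes. The solid line is the median of 35.3% and the dashed line the 12.4% expected with no slide effect.

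The comparison of animals with one another asked how far each transcript varied within slides and labelled sexes. The median probe had an SD of 0.24. The 5th percentile was 0.15, the 95th was 0.49 and the 99th was 0.69, on the deposited log scale. An SD over 1 was found for 13 probes. CB286695.1_1794 varied most, with an SD of 1.91, followed by BP439119.1_662 at 1.33 and CF175718.1_2364 at 1.31. For CB286695.1_1794 and CF175718.1_2364 most of this came from the gap between their classes, which removing labelled sex left in place. Within the lower and the upper class, SDs of deposited values were 0.365 and 0.226 for CB286695.1_1794, and 0.23 and 0.12 for CF175718.1_2364. Of the 100 most variable probes, 86 were also among the first 100 by median absolute deviation, 94 after quantile normalisation and 73 with slide differences kept. The first principal component of the adjusted values held 9.12% of their variance and the second 7.46%. These SDs contain measurement error, since each animal had 1 array.

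Animals fell into separate clusters for 2.07% of 7839 probes, 145 probes with 2 clusters and 17 with 3. After slide and labelled sex were removed, BP153836.1_434 had the largest BIC gain for a split, with 26.2% of arrays in its lower cluster (exact 95% interval 21.5 to 31.3%, n = 325). CF179208.1_1029 came next, with 21.02% of arrays in its upper cluster (exact 95% interval 16.6 to 25.8%, n = 325). The smaller cluster of CF179208.1_1029 was spread unevenly, with 1 of the 71 arrays on slides 45 to 53 and 68 of the 254 others (26.8%), a range picked after the values had been seen. Over all slides, a permutation test of unequal counts gave p = 0.064 for CF179208.1_1029 and p = 0.997 for BP153836.1_434. On the deposited values the same test gave p = 0.005 and p = 0.943. For CF179208.1_1029 the counts changed on slide 1 only, from 0 of 7 arrays after removal to 6 of 7 on the deposited values. Their cluster means lay 4.41 and 4.21 within-cluster SDs apart. On the deposited values, without that removal, classes of other probes stood further apart, such as those of CF175718.1_2364 with means of -1.64 (SD 0.23) and 1.14 (SD 0.12). By correlation, these probes formed 14 groups of 2 or more and 45 stood alone. The largest group held 76 probes, and a group of 7 contained CB286695.1_1794, AJ938358.1_528 and CF175718.1_2364. The count depended on the separation asked for, with 425 probes at 2 SDs and 5 probes at 4 SDs, and rose to 392 when slide differences were kept.

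**Figure D4:**
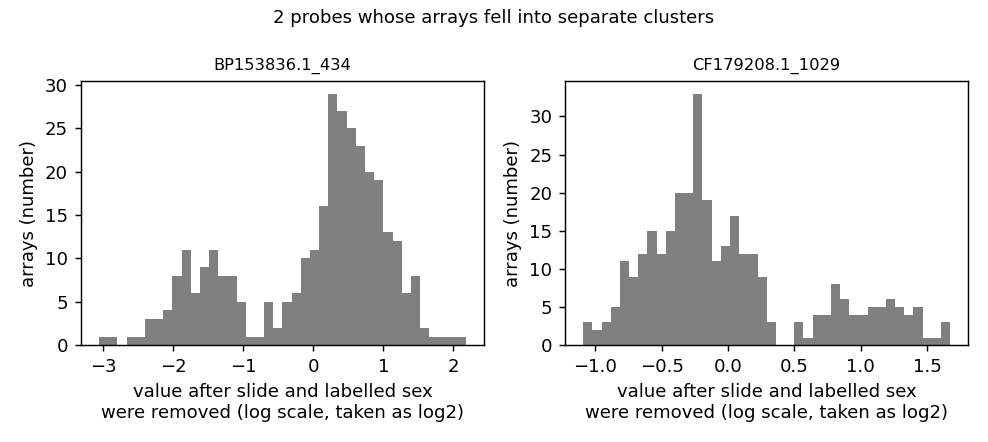
Number of arrays (y axis) by value after slide and labelled sex were removed (x axis, deposited log scale taken as log2) for BP153836.1_434 and CF179208.1_1029. The smaller clusters, of 26.2% and 21.02% of arrays, lie at the low and at the high end.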

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

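The regression on slide means and the averaging of probes of one sequence name were chosen after the data had been seen. The 7 probes of the sex comparison fell to 1 with no slide term and to 1 with a Welch test, neither among the 7, and to 0 with slide as a random block (290 probes at an unadjusted p under 0.05 in limma, consensus correlation 0.283). The count was 0 on slides 1 to 11 alone (201 at an unadjusted p under 0.05), where fewer arrays entered. It was 4 on slide means and 4 with a difference over 0.2 required. Other settings gave 5 to 8, and leaving out 1 slide at a time also gave 5 to 8. All 4 named probes turned direction on slide means, to -3.96, -1.75, 2.77 and 0.40 for CB286695.1_1794, AJ938358.1_528, CF175718.1_2364 and BQ597859.1_1820. CB286695.1_1794, AJ938358.1_528 and CF175718.1_2364 kept direction and call in 10 of 15 alternatives and lost the call in 4, and BQ597859.1_1820 kept them in 9 and lost the call in 5, one of them the required difference of 0.2 (limma with Benjamini-Hochberg, or Welch; adjusted p up to 0.999). All 4 kept both with each of the 41 slides left out. Without the slide term the differences of the 4 named probes were 0.35, 0.21, -0.24 and -0.06 in that order. A fit without slide pools the directions within and between slides, which were opposite for these probes. The cause of the calls lost without the slide term was not tested beyond these values. Separate clusters were counted for 425 probes at 2 SDs, 5 at 4 SDs and 392 with slide differences kept, and quantile normalisation moved the count by less than 1.5 times. The slide counts (7286 to 7368) and the median SD (0.22 to 0.29) stayed near their values of 7369 and 0.24. The alternatives that need gene names were not run, nor were those for gene lists. Signal over background was not used here, so what dim spots limit is not known.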

Other observations

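Except for the 3 counts of random splits and the test of array scaling, the tests in this part were chosen after the values they rest on had been seen. Probes designed to one sequence followed each other closely across animals. Over 346 pairs of probes that share a sequence name, the median correlation across arrays was 0.928 after slide and labelled sex were removed, with quartiles of 0.723 and 0.969. Among 9988 random pairs of other probes the median was -0.001 and the 95th percentile 0.284. The median was 0.975 in the brightest 25% of the pairs and 0.532 in the dimmest 25%. Only 4 of these pairs held a probe with separate clusters, and in 0 of them did both probes split the animals. One pair had an r of 0.909 and another 0.019, so a split seen by 1 probe was not always shared by its partner.

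Of 100 splits of the arrays into groups of the labelled sizes, the real one included, 2 gave 7 or more probes, and the highest other split called 95. When labels were shuffled only within slides, as the blocked test asks, 1 of 100 splits, the real one, gave 7 probes. The highest other gave 1, so chance is excluded at the 0.05 level as the source of the count. At least 4 of the 7 follow the same array classes, so the count does not show 7 separate sex differences. The split with 95 probes ignored slides and was looked at because it called the most. Its groups differed on principal component 4 by more than every shuffled split drawn for comparison. On components 1, 2 and 3 they stood at percentiles 44.6, 74.7 and 93.45. Its 95 probes had a median absolute correlation of 0.377 with component 4, and 0 of them lay in the group of 76. A split chosen for many calls can be aligned with some component by that choice, so no structure of the samples is concluded from it. For the slide comparison 1 of 100 splits, the real one, gave 7369 probes, and the highest other split gave 4, so chance is excluded there too.

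Sex labels and array classes disagreed in a way that labels or value columns exchanged between arrays of the same slide could produce on most slides. The 5 slides whose counts differed by 1 cannot come from such an exchange alone. The 36 slides with equal numbers of low arrays and arrays labelled male compare with a mean of 7.97 and a maximum of 21 in 100000 shuffles of the classes over arrays (one-sided p = 1.0e-05, the smallest they can give). Classes with nothing to do with the labels are excluded by the r of 0.971 across slides. A sex code inverted on whole slides is excluded for the 29 of 40 slides with both labelled sexes that matched in part. Inversion stays open for the 9 on which no array matched. On 8 of them, with 4 arrays of each labelled sex, inversion and exchange give the same numbers. Slide 1, the remaining one, held 3 arrays labelled male, 4 labelled female and 4 low arrays. Inversion gives these numbers there and an exchange alone does not. Labels exchanged fully at random within slides are argued against by the count above. There 1 of 100 splits shuffled within slides, the real one, called as many as 7 probes. At least 4 of the 7 follow the same classes and so are not separate evidence. BQ597859.1_1820, which has no gap, also ran lower on low arrays of slide 36, for example, at -0.16 to 0.13 against 0.34 to 0.53. The low arrays there were those labelled female, so that slide cannot tell the classes from the labels. On slides 10 and 33 the low arrays were those labelled male. They ran lower too, at 0.24 to 0.45 against 0.67 to 0.88 and at 0.24 to 0.34 against 0.61 to 0.85. On slide 8, however, a low array at 0.74 lay above a high one at 0.70. That relation was not tested over all slides. Whether labels or values moved stays open, and no biological explanation was tested.

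The 76 probes that clustered together were bright, at the 96.9th percentile of mean value in the median, with a median pairwise r of 0.913. They had 6.66% of cells empty, against 1.63% for 1134 other bright probes. Those others were all taken from a brightness upward that most of the 76 reached. Many were dimmer than the median probe of the block, so the sets were not matched for brightness. With slide differences kept, the mean level of the 76 probes was divided at a midpoint, which placed 57 arrays on the upper side. A slide-wide effect as the only source is argued against by 28 slides that held arrays of both sides. A part played by slides stays open, since a midpoint can also divide a slide whose level is shifted. With slide differences kept, 38 of the 76 probes were still counted. The scaling of the arrays may account for part of the pattern, since 19 of the 76 were still counted after quantile normalisation and their median SD moved from 0.48 to 0.32. Rejected spots stay open, as does what else moves with the block, and no biological explanation was tested, since the clusters were not compared with labelled sex or the animal number series.

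For 324 arrays, the mean level of the 76 probes after slide and labelled sex were removed was divided at a midpoint. Both sides are called the lower and the upper cluster here. They are not the mixture clusters, whose upper share had a median of 10.1%, so the upper side can hold arrays of both mixture clusters. Within these sides, 6 relations in all of the mean level were computed. Their permutation p-values were adjusted by the Benjamini-Hochberg method over the 6. Against the percentage of the block's own cells empty, Pearson's r was 0.204 (p = 8.0e-04, adjusted 0.002) and Spearman's rho 0.214 (p = 5.4e-04, adjusted 9.4e-04) in the 255 arrays of the lower cluster. In the 69 arrays of the upper cluster they were 0.382 (p = 0.001, adjusted 0.002) and 0.408 (p = 4.7e-04, adjusted 9.4e-04). Against the percentage of other probes' cells empty, r was 0.088 (p = 0.162, adjusted 0.194) and rho 0.165 (p = 0.008, adjusted 0.010) in the lower cluster. In the upper cluster r was 0.363 (p = 0.002, adjusted 0.003) and rho 0.404 (p = 6.3e-04, adjusted 9.4e-04). Against the mean level of the 1134 other bright probes, r was 0.398 and rho 0.383 in the lower cluster (each p = 1.0e-05, the smallest that the resamples can give, adjusted 6.0e-05). In the upper cluster r was -0.085 (p = 0.488, adjusted 0.488) and rho 0.042 (p = 0.730, adjusted 0.730). Without the 2 arrays farthest from the median level, r in the lower cluster was 0.209, 0.091 and 0.387 for these measures, and in the upper cluster 0.362, 0.306 and -0.014.

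A variant that splits an F2 generation 1 to 3 could give smaller clusters of 25%. Only that proportion was tested, and genetic splits of other proportions or into 3 clusters stay open. Outside the group of 76 and the group of 7, 63 probes had 2 clusters, and the exact 95% interval of the smaller share held 25% for 6 of them and excluded it for 57. With correlated probes counted once, by the probe with the largest BIC gain, it held 25% for 5 of 46 and excluded it for 41. The median smaller share was 7.8%, and 47 of the 63 lay under 15%. Such a split is therefore argued against for most of these clusters, as far as intervals that treat animals as independent can show, while BP153836.1_434 at 26.2% and CF179208.1_1029 at 21.02% are among the 6 and remain open, the latter with 1 of 71 arrays on slides 45 to 53 in its smaller cluster, so that its pooled share may not hold for every slide.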
